A study of Arabidopsis thaliana with 9 samples.

How the data were processed

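RNA from Arabidopsis seedlings was hybridised as biotin-labelled cRNA to 9 Affymetrix arrays, 3 each for the OsSAP11 line, the OsRLCK253 line and untransformed wild type. The deposited values are intensities, 1 signal per probe set and array, on a linear scale. The submitters' processing notes name GCOS, and the summarisation method, the background correction and the scaling of the arrays are not given in the sources used here. The values were checked for their scale, and signals ranged from 3.17 to 43695 over the 9 arrays. The array medians on the log2 scale differed by 0.0777, under the limit of 0.1 set for using the values as deposited, so no further scaling was applied.

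The table holds 22810 probe sets. The 64 control probe sets were set aside and the other 22746 were tested with no filter on signal. Of these, 13513 name exactly 1 gene, 503 name several and 8730 have no gene name in the tables used. Of the 13513, 13436 matched the RefSeq gene table of assembly TAIR10.1 and 77 did not. That table was used only for names and for the order of neighbouring genes. After matching, 1580 probe sets carry a gene symbol and 11933 a locus code alone. The measured genes number 13286, of which 144 have more than 1 probe set.

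Signals were transformed as log2(signal + 16). A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (6 residual degrees of freedom, prior degrees of freedom 0.773). The 3 contrasts were each line minus wild type and the OsSAP11 line minus the OsRLCK253 line. All p values are two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested, and a call needs an adjusted p under 0.05. Fold sizes are those of the transformed values, so that 16 added to each signal makes them smaller for dim probe sets. Errors are the standard deviation of 3 arrays for signals and the standard error of the model for log2 changes. The number of arrays limits the precision. As tested on simulated data, with changes of 0.5, 1 and 2 on the log2 scale added to 67, 67 and 66 of the 22746 probe sets, these were recovered for 55.2%, 88.1% and 100% of the changed probe sets in the first comparison, 70.1%, 89.6% and 100% in the second and 64.2%, 86.6% and 100% in the third. Of the 22546 unchanged probe sets, 0.0444%, 0.0577% and 0.0577% were called. The simulated noise was normal and independent, with the fitted spread, and far fewer probe sets were changed than were called in the data. These shares therefore check the procedure and do not give its power or error rate on the real arrays.

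Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a later section says that an item was chosen after the data were seen. The rule takes probe sets that name exactly 1 gene, have an adjusted p under 0.05, have the 3 arrays of one group all above those of the other and have a higher group mean above the median of all probe sets. Of these it names the 12 largest rises and falls in each comparison with wild type, the 5 largest in each direction between the lines, and the 5 largest called in both lines higher, lower or in opposite directions. Up to 4 members per gene list may be named, and all members of the SAP family and of the reference genes.

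Of 23 gene lists with 444 genes, 71 genes were measured by a probe set that names them. The 13 lists with at least 3 measured genes were tested, 5 lists had 1 or 2, and 5 had 0 (abscisic acid, phosphate starvation, nitrate, flower and seed lists). Beside the count of members called over all probe sets stands the count adjusted over the list alone. fry tests whether the genes of a list move on balance in one direction, camera was run with a preset correlation of 0.01 and with an estimated correlation, and p values were adjusted over the lists of a comparison. No call of camera with the preset correlation held with an estimated correlation in any comparison. fry does not compare a list with other genes. Families by keyword were not run, since the tables hold no gene descriptions.

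The overlap of the 2 lines was set against independent calls and against 100 simulations of unchanged groups that share the wild type arrays. Control probe sets were compared by two-sided exact permutation tests. Replicate numbers were checked for pairing by the correlation of deviations from the group means, and they did not pair the arrays. Principal components used the 1000 probe sets of largest variance. The order of genes along chromosomes was searched in windows of 20 measured genes against 10000 random orders. Alternatives were quantile normalization, median centring, pseudocounts of 1 and 32, a filter on dim probe sets, a fit of 2 groups alone, a trend with a robust prior, weights per array, replicate number as a block, a statistic per probe set with no shared spread, other thresholds, and each array left out in turn. Expression of the transgenes was not analysed here.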

Results

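Transcript levels were measured on 9 Affymetrix arrays in untreated Arabidopsis thaliana seedlings that were 21 days old and had grown on MS medium without antibiotic selection. The arrays form 3 groups of 3. One group is untransformed wild type, one is line 22 carrying the rice gene OsSAP11, and one is line 25 carrying the rice gene OsRLCK253. OsSAP11 encodes a stress-associated protein (SAP) with A20 and AN1 zinc fingers, and OsRLCK253 encodes a receptor-like cytoplasmic kinase. The labels call the replicates biological. The transgenes are rice genes and were not checked on this array. Each transgene is represented by 1 line, so the effect of the line and the effect of the transgene cannot be told apart. Every array holds 22810 probe sets, of which 64 are controls and 22746 were tested. The median signal per array ranged from 43.2 to 46.5, and 39.8% to 40.3% of the probe sets on an array had a signal under 16. The number of arrays limits the precision of every value.

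The 3 groups separated on the array profiles. Across probe sets, which are not independent replicates, the correlation of log2 signals was 0.993 to 0.997 within groups. It was 0.986 to 0.993 between the 2 transgenic lines, 0.977 to 0.983 between the OsSAP11 line and wild type, and 0.973 to 0.980 between the OsRLCK253 line and wild type. The first principal component held 76.4% of the variance of the 1000 most variable probe sets. Wild type arrays lay between 29.8 and 35.4 on it, and the arrays of both lines lay between -23.1 and -10.2. The control probe sets also moved with the groups. All 18 probe sets for the hybridisation spike-ins, which are transcripts added in fixed amounts, were lower in the OsSAP11 line than in wild type. Their median log2 difference was -0.26, with a range from -0.43 to -0.039. All 18 were lower in the OsRLCK253 line as well, with a median of -0.17 and a range from -0.42 to -0.018. These probe sets repeat the same few transcripts (bioB, bioC, bioD and cre), so they are not 18 independent observations. Of 27 probe sets for the poly-A spike-ins, 19 were lower in the OsSAP11 line, with a median of -0.013, and 16 were lower in the OsRLCK253 line, with a median of -0.03. Of 2 probe set pairs for the 3' and 5' ends of actin, whose log2 ratio is a measure of RNA integrity, the AFFX-Athal pair had a ratio of 4.27 ± 0.020 (SD, n = 3) in wild type, 4.58 ± 0.073 in the OsSAP11 line and 4.5 ± 0.1 in the OsRLCK253 line. For each line the difference in this pair had p = 0.1 by a two-sided exact permutation test, the smallest value that 3 arrays against 3 allow. The 5' signal of this pair was nearly constant, with log2 means of 7.13, 7.12 and 7.13 in the 3 groups, so the ratio followed the 3' signal alone. The AFFX-r2-At pair for actin differed from wild type by -0.0078 in the OsSAP11 line (exact permutation p = 1) and by 0.068 in the OsRLCK253 line (exact permutation p = 0.6). Over 6 pairs for 3 transcripts (actin, GAPDH and ubiquitin, with 2 pairs each), 3 pairs had all arrays of both lines above those of wild type. These were the AFFX-Athal pair for actin and the AFFX-r2-At pairs for GAPDH, with differences of 0.13 in the OsSAP11 line and 0.16 in the OsRLCK253 line, and for ubiquitin, with 0.15 and 0.13 (exact permutation p = 0.1 each). The ratio was higher than in wild type for 3 pairs in the OsSAP11 line, with differences from -0.14 to 0.31, and for 5 pairs in the OsRLCK253 line, with differences from -0.13 to 0.22.

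The first comparison asks how seedlings of the OsSAP11 line differ from untransformed seedlings in the absence of stress. STZ (also called ZAT10, a zinc-finger repressor in stress responses) had a signal of 26.0 ± 21.5 (SD, n = 3) against 1310 ± 188 in wild type. Its log2 change was -5.09 ± 0.83 (SE, adjusted p = 0.0102). On 2 of the 3 arrays of the line its signal was under 16, near background, so the size of this change depends on the 16 added to the signals before the logarithm. The calmodulin-like gene CML38 fell from 504 ± 177 to 19.3 ± 7.03, and COR47, which encodes a cold-induced dehydrin, fell from 4510 ± 401 to 1280 ± 144. In the other direction, SAG29, a senescence-associated sugar transporter gene, rose from 18.5 ± 17.3 to 391 ± 52.8, and DFR, the dihydroflavonol reductase gene of anthocyanin synthesis, rose 4.43-fold from 69.1 ± 35 to 356 ± 124.

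Among the 12 largest rises by the rule for named genes, SAG29 had a log2 change of 3.66 ± 0.42 (SE, n = 3, adjusted p = 0.00314). AT1G13650 followed with 2.97 ± 0.24 (adjusted p = 0.00102), and its signal was 224 ± 51.9 (SD) against 14.2 ± 2.25 in wild type. AT5G03350 rose by 2.68 ± 0.67 (adjusted p = 0.0468), from 319 ± 317 to 1610 ± 64.4. The rises of AT2G32160, AT1G80130 and AT1G62290 were 2.53, 2.04 and 1.97, and those of AT1G69730, AT3G44450 and AT5G12050 were 1.86, 1.83 and 1.76. The 12 largest falls were each larger in size than all of these rises but that of SAG29, which exceeded some of the falls. AT4G29780 fell by 4.61 on the log2 scale (SE 0.36, adjusted p = 0.000914), from 665 ± 190 to 11.0 ± 0.669. AT4G27280 fell by 4.36 (SE 0.89, adjusted p = 0.0228) and AT3G04640 fell by 4.22 (SE 0.26, adjusted p = 0.000541). CML38 fell by 3.85 (SE 0.34, adjusted p = 0.00129). AT3G15450 had the highest wild type signal of these genes, 10700 ± 544, and its signal in the line was 918 ± 417. The other 6 genes, AT1G72900, AT5G46710, AR781, AT1G72920, AT1G32920 and AT1G19380, had log2 changes from -3.52 to -3.33.

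Of the fixed gene lists, 6 were called by fry, 4 of them lower and 2 higher. Of 5 measured genes responsive to cold, drought and salt, 3 fell and none rose (4 fell when adjusted over the list alone), with a median log2 change of -1.79 (adjusted p = 0.000286 by fry, adjusted p = 0.0644 with an estimated correlation). COR15B, a cold-regulated chloroplast protein gene, fell by 1.93 (SE 0.24), COR47 fell by 1.81 (SE 0.13) and LTI30, a dehydrin gene, fell by 1.79. COR15A had a log2 change of -1.04 (adjusted p = 0.113). Of 5 rapid stress response regulators, 3 fell and none rose (3 when adjusted over the list alone), namely STZ, CML38 and the transcription factor gene WRKY53, which fell by 2.67 (SE 0.28) from 145 ± 32 to 9.21 ± 3.49. The median of this list was -2.67 (adjusted p = 0.00017 by fry, adjusted p = 0.0644 with an estimated correlation). Of 7 heat shock and chaperone genes, 3 fell and none rose (3 when adjusted over the list alone). The small heat shock protein gene AT2G29500 fell by 1.67, Fes1A, an exchange factor of HSP70, fell by 1.29, and the immunophilin gene AT5G48570 fell by 0.90. The median of the list was -0.30 (adjusted p = 0.000286 by fry, adjusted p = 0.0644 with an estimated correlation). Of 6 measured members of the Arabidopsis SAP family, which share their zinc fingers with OsSAP11, 3 fell and none rose (5 fell when adjusted over the list alone), with a median of -0.47 (adjusted p = 0.000286 by fry, adjusted p = 0.0644 with an estimated correlation). These were AT3G52800 (SAP6), with -1.42, AT2G36320 (SAP4), with -0.84, and AT4G22820 (SAP9), with -0.56.

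Photosynthesis genes and flavonoid genes moved the other way. Of 5 photosynthesis genes, 3 rose and none fell (4 rose when adjusted over the list alone). LHCB4.2, a light-harvesting protein gene, rose by 0.74 ± 0.058 (SE) from 12100 ± 609 to 20200 ± 1390, RCA, the rubisco activase gene, rose by 0.36, and PRK, the phosphoribulokinase gene, rose by 0.24. The median of the list was 0.24 (adjusted p = 0.000286 by fry, adjusted p = 0.0644 with an estimated correlation). Of 5 genes of flavonoid and anthocyanin synthesis, 3 rose and none fell (4 rose when adjusted over the list alone), with a median of 1.80 (adjusted p = 0.0105 by fry, adjusted p = 0.285 with an estimated correlation). They were DFR, with 2.15 ± 0.36, UF3GT, an anthocyanin glycosyltransferase gene, with 1.95 ± 0.35, and the anthocyanin glucosyltransferase gene AT4G14090, with 1.80 ± 0.41. As measured facts beside all these groups, the hybridisation spike-in signals were lower in this line, and the 3' to 5' ratio was higher in 3 of 6 control pairs, by 0.31 for actin, 0.13 for GAPDH and 0.15 for ubiquitin, while the other actin pair differed by -0.0078.

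The other lists were not called by fry in this comparison. In the endoplasmic reticulum stress list of 3 genes, BZIP60, a transcription factor gene of the unfolded protein response, fell by 0.69 and CRT1b, a calreticulin gene, rose by 0.30 (1 in each direction also when adjusted over the list alone, adjusted p = 0.0941 by fry). The median of that list was 0.021 while its mean, -0.125, and its test were negative. Of 5 auxin responsive genes, HAT2 rose by 0.37 and IAA29 by 0.20, and none fell (2 rose when adjusted over the list alone, adjusted p = 0.0607 by fry). Here the median was -0.0064 while the mean, 0.11, and the test were positive. Of 8 cell wall genes, the expansin gene EXPA8 rose by 0.55 and none fell (1 when adjusted over the list alone), with a median of 0.040 (adjusted p = 0.294 by fry). None of the 3 oxidative stress genes, 3 jasmonate genes, 4 root genes and 3 reference genes passed the test, over all probe sets or adjusted over the list alone, and the lists had fry adjusted p values of 0.96, 0.157, 0.901 and 0.599. The control probe sets of the array, which are outside these lists, differed in log2 level from wild type. The differences were 0.319 to 0.495 for GAPDH, -0.0031 to 0.302 for actin and -0.0032 to 0.26 for ubiquitin. The oxidative stress list had a negative median, -0.016, and a negative mean, -0.087, with a positive test. In lists with 1 or 2 measured genes, which were not tested as lists, GI, a gene of the circadian clock and of flowering, fell by 0.67 (adjusted p = 0.0311). AT2G31790, of the glucosinolate list, rose by 0.45 (adjusted p = 0.0273). Both were also called when adjusted over the list alone. The genes SAG101 and GRX480 of salicylic acid defence, BHLH101 and PYE of iron deficiency, and the other measured gene of the glucosinolate list, BCAT4, had log2 changes of 0.049, -0.013, -0.38, -0.21 and 0.21 and did not pass. In the senescence list SAG29 rose, as given above, and WRKY6 had a log2 change of -0.19 and did not pass (1 rose when adjusted over the list alone).

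In total, 2869 probe sets (12.6%) differed between the OsSAP11 line and wild type at an adjusted p under 0.05 by limma. Of these, 1692 (59.0%) were higher and 1177 lower in the line. At least 2-fold differences were found for 588, and 215 of these were higher and 373 lower. At least 4-fold differences were found for 20 higher and 119 lower probe sets. In 31.7% of all tested probe sets the 3 arrays of one group lay outside the range of the other 3, against a share of 10% by chance. The share by chance assumes no shift common to many dim probe sets, so 31.7% does not count changed genes. Without OsSAP11 replicate 1, OsSAP11 replicate 2 or wild type replicate 1 the count was 1863, 1887 or 1827, and with a statistic per probe set with no shared spread it was 92. Of the genes named here, AT5G03350, HAT2, IAA29, GI, AT4G27280, AT4G14090, AT2G31790 and PRK lost their call in at least 5 of the 9 fits that left out 1 array.

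The second comparison asks the same of the OsRLCK253 line. Cold-regulated genes were among the genes most reduced in this line. COR27, a cold-regulated gene that acts in the circadian clock, had a signal of 15.1 ± 5.49 (SD, n = 3) against 858 ± 102 in wild type. Its log2 change was -4.82 ± 0.17 (SE, adjusted p = 5.66e-05), and since its mean signal in this line was under 16, near background, the size of the change depends on the 16 added to the signals. COR15B fell from 4660 ± 757 to 424 ± 123. DFR rose 9.06-fold to 730 ± 161, and UF3GT rose from 30.6 ± 15 to 350 ± 115. AFR, an F-box protein gene of phytochrome A signalling, rose from 89.8 ± 25.8 to 522 ± 134.

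The largest rise by the rule for named genes was that of AT5G03350, with a log2 change of 3.26 ± 0.67 (SE, n = 3, adjusted p = 0.0221). DFR rose by 3.18 ± 0.36 (adjusted p = 0.00216), UF3GT by 2.97 ± 0.35 (adjusted p = 0.00264) and AFR by 2.34 ± 0.23 (adjusted p = 0.00131). AT3G15310 rose from 4.95 ± 0.52 (SD) to 102 ± 36.1, a log2 change of 2.44 with 16 added to each signal. SAG29 rose by 2.19 ± 0.42 (adjusted p = 0.0166) to a signal of 140 ± 72.0. The other rises were AT1G69730, AT4G14090, AT1G13650, AT3G44450, AT2G32160 and AT2G15020, with log2 changes from 2.21 to 2.75. Among the 12 largest falls, AT3G15450 fell by 4.6 (SE 0.29, adjusted p = 0.000312) to a signal of 429 ± 63.1. AT1G07050 fell by 4.5 (SE 0.17, adjusted p = 5.66e-05), from 634 ± 61.8 to 12.9 ± 4.88. AT5G62360 fell by 4.16 (SE 0.13, adjusted p = 3.99e-05), from 765 ± 65.2 to 27.7 ± 1.03. AT4G29780 fell by 4.14 to 24.5 ± 19.5, and STZ fell by 3.59 (SE 0.83, adjusted p = 0.0331) to 148 ± 156. COR15B fell by 3.43 (SE 0.24, adjusted p = 0.000389). The remaining AT4G33980, AT5G46710, AT3G04640, AT1G11210 and AT3G15630 had log2 changes from -3.80 to -3.42.

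Here 7 of the fixed lists were called by fry, 4 of them lower and 3 higher. Of the 5 cold, drought and salt genes, 4 fell and none rose (4 when adjusted over the list alone), with a median of -1.53 (adjusted p = 0.000299 by fry, adjusted p = 0.0801 with an estimated correlation). COR47 fell by 1.80, COR15A fell by 1.53 and LTI30 fell by 1.45, and LEA4-5 had a log2 change of -0.052 and did not pass. Of the 5 rapid stress response regulators, 3 fell and none rose (3 when adjusted over the list alone). CML38 fell by 2.82 and WRKY53 fell by 2.47, and the median of the list was -2.47 (adjusted p = 0.000522 by fry, adjusted p = 0.1 with an estimated correlation). Of the 7 heat shock and chaperone genes, 3 fell and none rose (3 when adjusted over the list alone), with a median of -0.22 (adjusted p = 0.00262 by fry, adjusted p = 0.1 with an estimated correlation). That median was -0.13 without wild type replicate 2 and -0.36 without wild type replicate 3. Fes1A fell by 1.17, AT2G29500 fell by 1.14 and AT5G48570 fell by 0.83. Of the 6 SAP family genes, AT2G36320 (SAP4) fell by 0.95 and AT4G22820 (SAP9) fell by 0.38, and none rose (4 fell when adjusted over the list alone). The median of the family was -0.33 (adjusted p = 0.000498 by fry, adjusted p = 0.0801 with an estimated correlation), and AT3G52800 (SAP6) had a log2 change of -0.93 (adjusted p = 0.0528).

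Of the 5 photosynthesis genes, 3 rose and none fell (5 rose when adjusted over the list alone), with a median of 0.24 (adjusted p = 0.000299 by fry, adjusted p = 0.1 with an estimated correlation). LHCB4.2 rose by 0.78 to a signal of 20700 ± 600 (SD, n = 3), RCA by 0.48 and PRK by 0.24. Of the 5 flavonoid and anthocyanin genes, 4 rose and none fell (5 rose when adjusted over the list alone), with a median of 2.73 (adjusted p = 0.000498 by fry, adjusted p = 0.186 with an estimated correlation). UGT78D2, a flavonoid glucosyltransferase gene, rose by 1.02, from 271 ± 26.2 to 564 ± 28.7. Of the 8 cell wall genes, the expansin genes EXPA4 and EXPA8, which loosen the wall, rose by 1.015 and 0.79, and none fell (3 rose when adjusted over the list alone). The median of that list was 0.050 (adjusted p = 0.0132 by fry, adjusted p = 0.689 with an estimated correlation). With 1 array left out the median ranged from 0.0085 to 0.127. The list was not called by fry with replicate number as a block (adjusted p = 0.0846), nor by camera with the preset correlation (adjusted p = 0.392). Beside these groups, the hybridisation spike-in signals were lower in this line, and the 3' to 5' ratio was higher in 5 of 6 control pairs, by 0.22 and 0.068 for actin, 0.16 for GAPDH and 0.13 and 0.16 for ubiquitin.

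Lists not called by fry here were the endoplasmic reticulum stress list (adjusted p = 0.0796), in which BZIP60 fell by 0.48 and CRT1b rose by 0.67, 1 in each direction also when adjusted over the list alone. Its median was -0.034, its mean was 0.051 and its test was positive. Of the 3 oxidative stress genes, SAPX, a stromal ascorbate peroxidase gene, rose by 0.70 and none fell (1 when adjusted over the list alone), with adjusted p = 0.0521 by fry. Of the 5 auxin responsive genes, HAT2 fell by 0.35 and none rose (2 fell when adjusted over the list alone), with adjusted p = 0.142 by fry. Of the 4 root genes, EXPA7, a root hair expansin gene, rose by 0.74 and none fell (1 when adjusted over the list alone), with adjusted p = 0.141. None of the 3 jasmonate and 3 reference genes passed, over all probe sets or over the list alone, with adjusted p = 0.859 and adjusted p = 0.711. The control probe sets of the array differed in log2 level from wild type by 0.452 to 0.748 for GAPDH. For actin the differences were 0.0022 to 0.226 and for ubiquitin -0.14 to 0.0841. The jasmonate list had a negative median, -0.026, and a negative mean, -0.085, with a positive test. Among the lists too small to test, GI fell by 1.69 from 440 ± 7.2 to 126 ± 11.3 (adjusted p = 0.000868), and AT2G31790 rose by 0.48 (adjusted p = 0.0209). When adjusted over the list alone, GI was called and both glucosinolate genes rose. SAG101, GRX480, BHLH101, PYE, BCAT4 and WRKY6 had log2 changes of 0.012, 0.15, -0.45, -0.34, 0.31 and -0.13 and did not pass over all probe sets.

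The counts were of similar size to those of the first comparison. By limma, 3138 probe sets (13.8%) differed at an adjusted p under 0.05, 1581 (50.4%) of them higher and 1557 lower in the OsRLCK253 line. At least 2-fold differences were found for 764, with 290 higher and 474 lower, and at least 4-fold differences for 53 higher and 131 lower probe sets. The groups did not overlap in 46.4% of the tested probe sets, against 10% by chance, a share that assumes no shift common to many dim probe sets. The lower quartile of signal was 5.95 to 6.41 on the arrays of this line and 5.68 to 5.91 on the wild type arrays, so 46.4% does not count changed genes. Without wild type replicate 1 the count was 2040, with weights per array it was 5694, and with a statistic per probe set with no shared spread it was 127. The cell wall call was lost without wild type replicate 3 (adjusted p = 0.0538), and EXPA4, EXPA7, HAT2, COR15A, STZ and AT2G29500 lost their call in at least 5 of the 9 fits that left out 1 array.

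**Figure D1:**
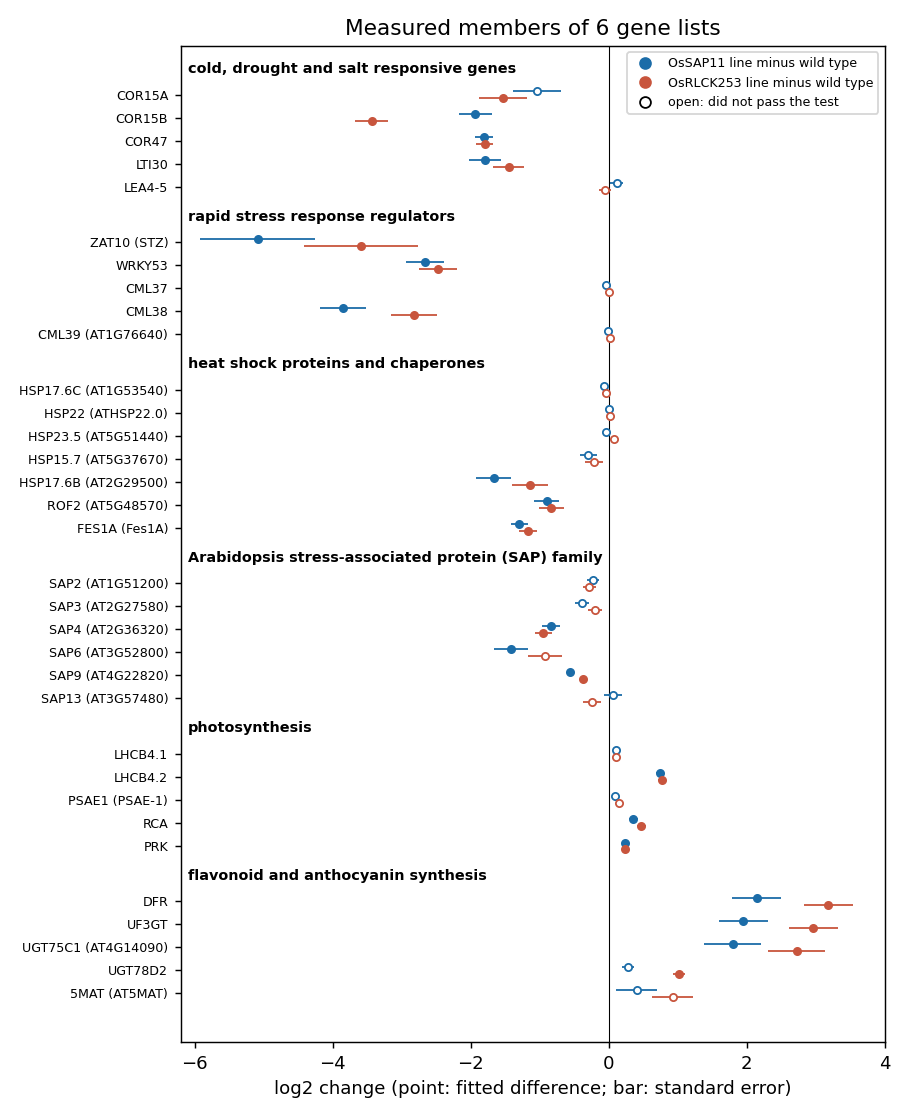
Log2 change of each measured member of 6 gene lists, OsSAP11 line (blue) and OsRLCK253 line (red) minus wild type, with points for the fitted difference, bars for the standard error and open points for members that did not pass the test. COR15B lies at -1.93 in the OsSAP11 line and at -3.43 in the OsRLCK253 line.

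The third comparison sets the lines against each other and asks where they differ, with a test of the difference itself. COR27 was higher in the OsSAP11 line, with a signal of 147 ± 28.7 (SD, n = 3) against 15.1 ± 5.49 in the OsRLCK253 line, a log2 difference of 2.39 ± 0.17 (SE, adjusted p = 0.00321). COR15B was higher by 1.5 (adjusted p = 0.0206) and GI by 1.02 (adjusted p = 0.0168), and all 3 genes had fallen in both lines against wild type. TRY, a MYB repressor of trichome formation, was lower in the OsSAP11 line, with 21.0 ± 3.57 against 102 ± 11.6 and a log2 difference of -1.68 ± 0.14 (adjusted p = 0.00411). UGT78D2 had a log2 difference of -0.74 (adjusted p = 0.00913), with 332 ± 29.1 against 564 ± 28.7.

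The other genes most elevated in the OsSAP11 line were AT1G07050, with a log2 difference of 2.08 ± 0.17 (adjusted p = 0.00375), AT1G11210, AT1G56300 and AT1G52000, with 2.01, 1.87 and 1.86. The genes most reduced in it were AT4G33720, with -3.14 ± 0.68 (adjusted p = 0.0498), AT5G14650, AT3G55710 and AT3G28500, with -1.69, -1.67 and -1.66. AT4G33720 had a signal of 8.83 ± 3.88 in the OsSAP11 line and 222 ± 109 in the OsRLCK253 line, and lost its call in 8 of the 9 fits that left out 1 array, as did IAA29, which is named among the lists.

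Among the fixed lists, 4 differed between the lines by fry. Of 5 flavonoid and anthocyanin genes, UGT78D2 differed and was lower in the OsSAP11 line, and none was higher (3 lower when adjusted over the list alone), with a median difference of -0.93 (adjusted p = 0.0321 by fry, adjusted p = 0.47 with an estimated correlation). Of 5 auxin responsive genes, HAT2 and IAA29 were higher in the OsSAP11 line and none was lower (3 higher when adjusted over the list alone), with a median of 0.22 (adjusted p = 0.0248 by fry, adjusted p = 0.47 with an estimated correlation). Of 3 endoplasmic reticulum stress genes, CRT1b was lower in the OsSAP11 line, with -0.38, and none was higher (2 lower when adjusted over the list alone), with a median of -0.21 (adjusted p = 0.0248 by fry, adjusted p = 0.47 with an estimated correlation). For the 5 rapid stress response regulators the median was -0.20 (adjusted p = 0.0321 by fry, adjusted p = 0.47 with an estimated correlation), and by limma 0 of them differed, over all probe sets or adjusted over the list alone. Each of these 4 calls was lost without OsSAP11 replicate 2, with adjusted p = 0.0807 for the rapid stress and the flavonoid list, 0.0719 for the auxin list and 0.0518 for the endoplasmic reticulum list, and without OsRLCK253 replicate 1, with adjusted p from 0.0503 to 0.106. All 4 were also lost when the lines were fitted without the wild type arrays (adjusted p = 0.0503 each), and the rapid stress call was lost in 7 of the 9 fits that left out 1 array. The rapid stress median ranged from -0.3845 to -0.0396 over these 9 fits and was -1.026 with the filter on dim probe sets.

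The remaining lists were not called between the lines. COR15B was the 1 member of the cold, drought and salt list that differed (1 when adjusted over the list alone, adjusted p = 0.0773 by fry). No member of the SAP family differed, and 1 was lower in the OsSAP11 line when adjusted over the list alone (median -0.063, adjusted p = 0.335 by fry). The heat shock, oxidative stress, jasmonate, photosynthesis, cell wall and root lists had median differences of -0.082, -0.36, -0.66, -0.037, -0.26 and -0.33, with fry adjusted p values from 0.068 to 0.42. The reference genes had a median of 0.056, with a negative test (adjusted p = 0.847).

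By limma, 1185 probe sets (5.21%) differed between the lines, 760 (64.1%) of them higher and 425 lower in the OsSAP11 line, and 143 differed at least 2-fold. After median centring of the arrays 50.5% of 1642 were higher, with weights per array 38.3% of 5201, with a trend and a robust prior 49.8% of 1809, and without OsRLCK253 replicate 1 48.6% of 1388. The groups did not overlap in 50.6% of the tested probe sets, against 10% by chance. The 10% assumes no shift common to many dim probe sets. The lower quartile of signal was 5.63 to 5.78 on the OsSAP11 arrays and 5.95 to 6.41 on the OsRLCK253 arrays. The share of 50.6% is therefore no measure of how many genes differ in expression. Without OsSAP11 replicate 1, 2 or 3 the count was 564, 485 or 449, and the other alternatives that moved it most gave 5201 as above and 0 with a statistic per probe set with no shared spread, for which 5031 had an unadjusted p under 0.05.

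The same arrays allow the changes of both lines against wild type to be set side by side. AT5G03350, DFR, SAG29, AT1G13650 and AT2G32160 rose in both lines, and STZ, AT4G29780, AT3G15450, AT3G04640 and AT5G46710 fell in both. For several of these the lines did not pass the test of their difference, for example AT5G03350, with -0.58 (adjusted p = 0.566), DFR, with -1.03 (adjusted p = 0.139), and STZ, with -1.5 (adjusted p = 0.28). Across all probe sets, 881 were higher in both lines and 799 lower in both, and 182 of these 1680 also differed between the lines. If the calls of the lines were independent, 118 and 80.6 would be expected. Changed in opposite directions were 26 probe sets, and 11 of these name 1 gene. All 26 also differed between the lines, which follows from 2 calls of opposite sign with the same standard error and is no separate result. Without wild type replicate 1, 2 or 3 the genes called in opposite directions were 9, 11 or 13, and the genes higher in both lines fell from 881 to 543 without wild type replicate 1 and to 579 without OsSAP11 replicate 1.

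The genes with opposite changes included FDH, the formate dehydrogenase gene, which rose by 0.66 in the OsSAP11 line and fell by 0.47 in the OsRLCK253 line. Its signals were 3670 ± 433 and 1660 ± 118 (SD, n = 3), against 2300 ± 150 in wild type, and the difference was 1.13 (adjusted p = 0.00491). AT1G65490 fell by 0.60 in the OsSAP11 line and rose by 0.68 in the OsRLCK253 line, with 872 ± 132 and 2130 ± 166 against 1320 ± 115 and a difference of -1.28 (adjusted p = 0.00624). HAT2, a homeodomain-leucine zipper gene of the auxin list, rose by 0.37 and fell by 0.35. LSMT-L, a gene of the Rubisco methyltransferase kind, rose by 0.37 and fell by 0.32, and AT2G37480 rose by 0.29 and fell by 0.34.

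The log2 changes of the lines had a Pearson correlation of 0.796 and a Spearman correlation of 0.542 across probe sets, which are not independent replicates. Both changes were taken against the same 3 wild type arrays, which cannot be split into parts of 2 arrays each, so part of the excess may come from the shared controls. In simulations with no change in either line the shared controls gave a Pearson correlation of 0.5, a Spearman correlation of 0.438 and a covariance of 0.00707. The changes had the same sign in 55.1% of the probe sets, against 66.6% in the simulations. The observed covariance was 0.133, which is 0.126 above the simulated one. The simulations drew independent noise for each probe set, with no shift common to an array or a group. The remainder of 0.126 also holds any harvest difference of the wild type group. It is therefore not an estimate of an effect shared by the transgenes.

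**Figure D2:**
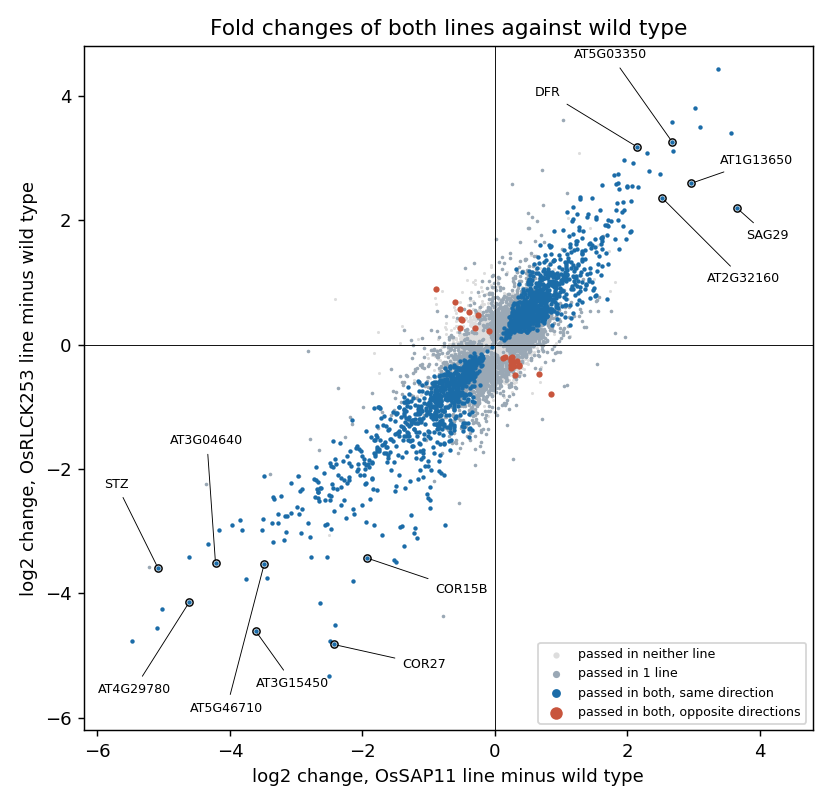
Log2 change of every tested probe set in the OsSAP11 line (x axis) and in the OsRLCK253 line (y axis), each minus wild type, coloured by whether the change passed the test in neither line, in 1 line, in both in the same direction (1680 probe sets) or in both in opposite directions (26 probe sets). STZ lies at -5.09 and -3.59, and DFR at 2.15 and 3.18.

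**Figure D3:**
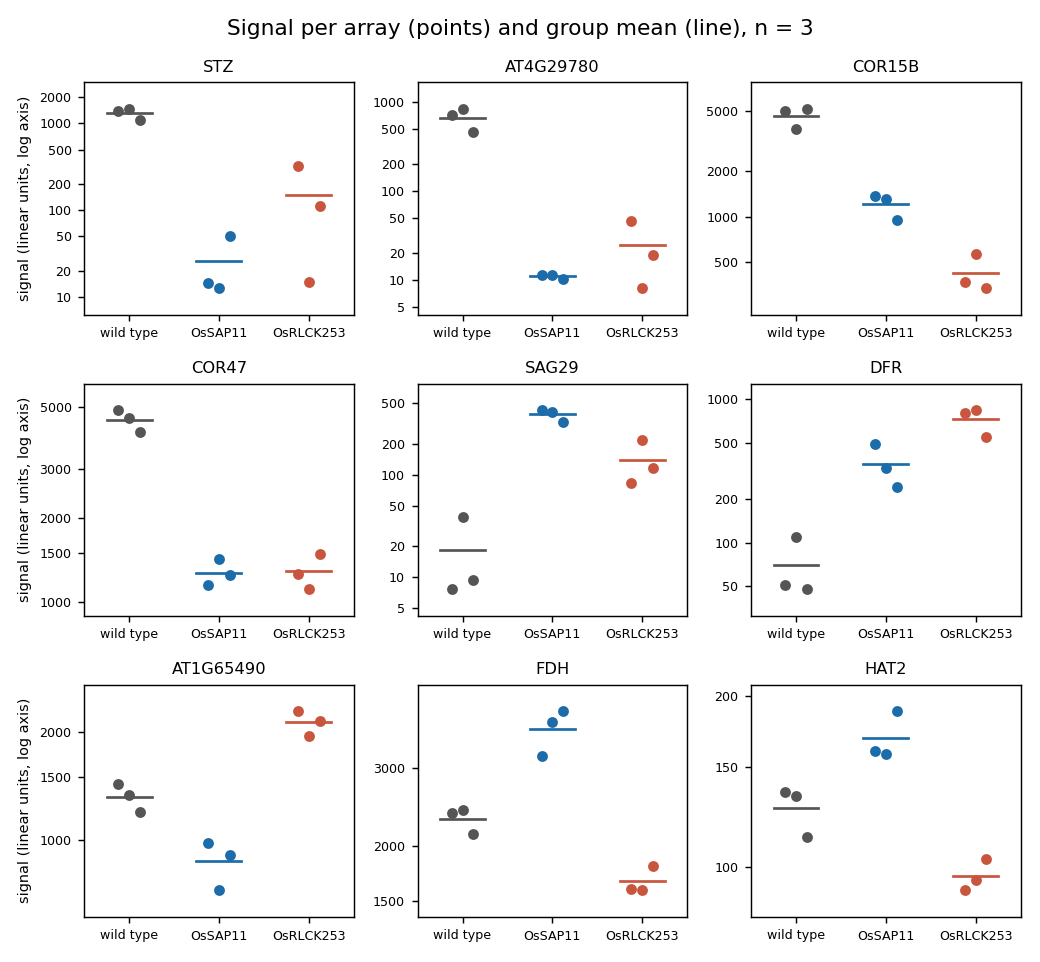
Signal per array (points, linear units on a log axis) and group mean (line) of 9 named genes in the 3 groups, with n = 3 each. FDH lies above its wild type level in the OsSAP11 line, with a mean of 3670, and below it in the OsRLCK253 line, with a mean of 1660.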

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

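Of the tests in this part, the comparison of the lines for the handling or time of day explanation was chosen only after the result was seen. The genes given here come from the probe sets for 1 gene that changed in opposite directions in the lines. They are the 5 whose smaller change against wild type was largest. They passed the direct test of the difference, as 1185 probe sets did in all, but this followed from their opposite calls and is no further support. The lists given are those called between the lines by fry.

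The first pattern is the lower level of cold and rapid stress genes in both lines, whose 10 measured members had median log2 changes of -1.80 and -1.66. A single unusual wild type array as the cause is excluded, since over both lines and each wild type array left out the median nearest to 0 was -1.618. Differences in the medians of the arrays are too small to account for the pattern, since these medians differed by 0.0777 on the log2 scale. After quantile normalization or median centring the median change nearest to 0 was -1.62. With array medians this close, median centring could not have given another outcome. These rescalings do not address the lower hybridisation spike-in signals of both lines. Harvest handling or time of day of the wild type seedlings may still account for the shared part, because any harvest difference is confounded with group, and of the 6 members called lower in both lines 1, COR15B, differed between the lines. That explanation and an effect of both transgenes cannot be told apart with these arrays, and the biological explanation was not tested further.

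The second pattern is a possible local cluster of differences between the lines. If an insertion or a differing chromosome segment were its source, genes that differ would gather in a window, and the densest window of 20 genes held 6, from AT2G19180 to AT2G19460, all lower in the OsSAP11 line. Random orders of the 13217 genes gave a median of 5, and 39% of them were as dense. A local effect of an insertion could therefore not be seen, and it cannot be told apart from chance, since an insertion that changes few genes would not raise the densest window.

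AT1G65490 changed in opposite directions in the lines, with a log2 difference of -1.282 between them. It lost its call against wild type for the OsSAP11 line in 3 of the 9 fits that left out 1 array. FDH changed in opposite directions with a difference of 1.131, and lost its call for the OsRLCK253 line in 4 of 9 such fits. HAT2 did so with 0.7155, and lost its call against wild type in 9 of 9 fits for the OsSAP11 line and in 7 of 9 for the OsRLCK253 line when 1 array was left out. LSMT-L did so with 0.697, and lost its call in the OsSAP11 line in 5 of 9 such fits and in the OsRLCK253 line in 4 of 9. AT2G37480 did so with 0.625, and lost its call in the OsSAP11 line in 4 of 9 such fits and in the OsRLCK253 line in 2 of 9.

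Of the fixed lists, 4 were called between the lines by fry (unadjusted p from 0.00213 to 0.00989), and none of them passed with an estimated correlation (adjusted p = 0.47 each by camera in limma). For the rapid stress response regulators the median difference was -0.1958, with 0 of 5 genes called, and the call of the list was lost in 7 of the 9 fits that left out 1 array. The median was 0.215 for the auxin responsive genes, with 2 of 5 called. It was -0.9275 for the flavonoid and anthocyanin genes, with 1 of 5 called, and -0.2076 for the endoplasmic reticulum stress genes, with 1 of 3 called. These 3 calls were lost in 2, 3 and 3 of the 9 fits.

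Other splits of the 6 arrays of a comparison into 3 against 3 number 10 with the real one, too few for a share under 0.05. The real split gave 2869 probe sets for the OsSAP11 line, and 1 of the 10 splits gave as many, with 1 as the highest of the others. For the OsRLCK253 line the real split gave 3138, with 2 as the highest other, and between the lines it gave 1185, with 0 as the highest other (limma, 1 of 10 each). Every other split mixes arrays of both groups, so a group difference adds to the spread within its parts and lowers its count. The low counts of the other splits therefore do not show what unchanged groups would give.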

How the results depend on the processing

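The alternative that left out probe sets with mean signals under 16 in both groups was chosen only after the data were seen. No fixed list called by fry and no called value of a named gene reversed its direction under any alternative, while the median of the SWEET family of the OsSAP11 line turned from 0.0072 to -0.011 after median centring. The share of higher probe sets among those that differ between the lines, 64.1%, was 38.3% with array weights, 49.8% with a trend and a robust prior and 48.6% without OsRLCK253 replicate 1. Among probe sets changed in the OsSAP11 line, 59.0% were higher, against 36.6% of those changed at least 2-fold and 42.4% with no shared spread, and in the OsRLCK253 line 50.4%, with a range from 38.0% (at least 2-fold) to 61.2% (array weights). Medians of some lists that were not called changed sign, among them the oxidative list of the OsRLCK253 line, from 0.303 to -0.06768 with array weights. The fry test of that list stayed positive. Of the lists called by fry, 145 of 153 values kept their call under alternatives other than leaving out an array, and 137 of 153 when 1 array was left out. Of the lists not called, 172 of 192 and 182 of 198 stayed so. Of 119 called values of named genes, 1892 of 2139 alternative values kept their call (88.5%), 247 lost it and 0 reversed, and 80 lost it in no fit that left out 1 array. Among the called sets, quantile normalization kept 90.0%, 93.1% and 83.5% of the calls of the OsSAP11 line, the OsRLCK253 line and their difference, and median centring kept 95.3%, 96.2% and 92.0%. Stricter thresholds give fewer calls by construction, and for the other alternatives the cause was not tested. Signal over background limits about 39.8% to 40.3% of the probe sets, which lie under 16. Averaging probe sets per gene was not run as its own value, since 0 list genes have more than 1 probe set, and 2 lists had no value under the filter on dim probe sets.

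In the order OsSAP11 line, OsRLCK253 line and their difference, a 2-fold change at an adjusted p under 0.05 gave 588 (215 higher, 373 lower), 764 (290 and 474) and 143 (92 and 51) probe sets, and at an unadjusted p under 0.05 it gave 619 (226 and 393), 808 (311 and 497) and 194 (99 and 95). An adjusted p under 0.01 gave 1195 (659 and 536), 1405 (650 and 755) and 205 (149 and 56). A statistic per probe set with no shared spread gave 92 (39 and 53), 127 (59 and 68) and 0 (0 and 0), with 4178, 4723 and 5031 at an unadjusted p under 0.05. The added filter under 16 gave 3521, 3711 and 1712 (1077 and 635).

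With array weights, which ranged from 0.3 to 3.07 within the OsRLCK253 line, the OsRLCK253 count was 5694 (3487 higher), the difference 5201 (1992 and 3209), opposite changes 69, the Pearson correlation 0.8213 and the covariance 0.1426. In that fit the endoplasmic reticulum list of the OsSAP11 line had a median of -0.009349 (adjusted p = 0.0336), the oxidative list of the OsRLCK253 line -0.06768 (adjusted p = 0.0427) and the rapid stress list between the lines -0.03431 (adjusted p = 0.114). The fry test of that oxidative list was positive, opposite to its median. After median centring the lines differed in 1642 probe sets, 812 of them lower. The endoplasmic reticulum medians were then 0.002756 (adjusted p = 0.0463) and -0.02012 (adjusted p = 0.00113) in the lines, and the oxidative median of the OsRLCK253 line was 0.3169 (adjusted p = 0.00821). The fry test of this endoplasmic reticulum list was negative in the OsSAP11 line and positive in the OsRLCK253 line, opposite to its medians. Between the lines the heat shock, oxidative and cell wall lists were called at -0.1135, -0.3935 and -0.2893 (adjusted p = 0.0377, 0.0227 and 0.0227).

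Without probe sets under the 40th percentile the lines differed in 1974 (1207 and 767), the Spearman correlation was 0.6574 and the covariance 0.2176. The endoplasmic reticulum list of the OsSAP11 line was 0.02057 (adjusted p = 0.0368), the oxidative and auxin lists of the OsRLCK253 line 0.303 (adjusted p = 0.0295) and -0.3478 (adjusted p = 0.0193), and the rapid stress list between the lines -1.026 (adjusted p = 0.186). The test of this endoplasmic reticulum list was negative, opposite to its median. With a trend and a robust prior the lines differed in 1809 (909 lower), opposite changes were 16, the oxidative list of the OsRLCK253 line was 0.303 (adjusted p = 0.0359), and between the lines the heat shock, oxidative and cell wall lists were -0.08179, -0.3618 and -0.2576 (adjusted p = 0.0459, 0.046 and 0.046). With the replicate block the lines differed in 639 (416 and 223), the counts against wild type were 2285 and 2556, and the cell wall list of the OsRLCK253 line was 0.04972 (adjusted p = 0.0846). The numbers did not pair the arrays, since deviations of arrays with the same number correlated at -0.127 to 0.181. With only the 2 groups compared the lines differed in 609 (405 and 204), 562 probe sets were higher in both, the endoplasmic reticulum list of the OsRLCK253 line was -0.034 (adjusted p = 0.0185), and the rapid stress, auxin, flavonoid and endoplasmic reticulum lists between the lines were -0.1958, 0.215, -0.9275 and -0.2076 (adjusted p = 0.0503 each). For the endoplasmic reticulum list of the OsRLCK253 line the test was positive, opposite to the median of -0.034.

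A pseudocount of 1 gave a covariance of 0.1882 and 0.3239 (adjusted p = 0.0499) for the oxidative list of the OsRLCK253 line, and a pseudocount of 32 gave a covariance of 0.1078. Quantile normalization gave 0.307 (adjusted p = 0.0165) and -0.0297 (adjusted p = 0.00387) for the oxidative and endoplasmic reticulum lists of that line, and -0.1396 (adjusted p = 0.0831) and -0.3821 (adjusted p = 0.0485) for the rapid stress and oxidative lists between the lines. The endoplasmic reticulum test of the OsRLCK253 line was again positive, opposite to its median. Over all these alternatives and the left-out arrays, the fry adjusted p ranged from 0.00685 to 0.912 and from 0.00113 to 0.418 for the endoplasmic reticulum list of the lines, from 0.000999 to 0.385 for the auxin list of the OsSAP11 line, from 0.00821 to 0.163 for the oxidative, from 0.0193 to 0.412 for the auxin, from 0.0202 to 0.669 for the root and from 0.00445 to 0.0846 for the cell wall list of the OsRLCK253 line. Between the lines it ranged from 0.0101 to 0.186 for the rapid stress, 0.00089 to 0.0719 for the auxin, 0.0105 to 0.106 for the flavonoid, 0.000781 to 0.0518 for the endoplasmic reticulum, 0.0366 to 0.312 for the heat shock, 0.0227 to 0.204 for the oxidative, 0.0217 to 0.583 for the jasmonate, 0.0146 to 0.95 for the SAP family, 0.0302 to 0.665 for the root and 0.0146 to 0.231 for the cell wall list.

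With an estimated correlation, camera gave an adjusted p of 0.0644 for the cold, rapid stress, heat shock, photosynthesis and SAP family lists of the OsSAP11 line and 0.285 for its flavonoid list. In the OsRLCK253 line it gave 0.0801 for the cold and SAP family lists, 0.1 for the rapid stress, heat shock and photosynthesis lists, 0.186 for the flavonoid and 0.689 for the cell wall list, and between the lines 0.47 for all 4 called lists. With the preset correlation it gave 0.392 for the cell wall list of the OsRLCK253 line, and 0.259, 0.237, 0.077 and 0.259 for the rapid stress, auxin, flavonoid and endoplasmic reticulum lists between the lines.

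Leaving out 1 array at a time gave 1827 to 2875 probe sets for the OsSAP11 line (1052 to 1693 higher, 775 to 1182 lower), with 1863, 1887 and 1827 without OsSAP11 replicate 1, OsSAP11 replicate 2 and wild type replicate 1. It gave 2040 to 3387 for the OsRLCK253 line (983 to 1915 higher, 1057 to 1472 lower), with 2040 without wild type replicate 1. The lines differed in 449 to 1388 (320 to 675 higher, 129 to 713 lower), with 564, 485 and 449 without OsSAP11 replicates 1, 2 and 3. The genes higher in both lines were 543 to 809, with 579 and 543 without OsSAP11 replicate 1 and wild type replicate 1, genes lower in both were 555 to 775, and genes called in opposite directions were 9 to 29, with 9, 11 and 13 without wild type replicates 1, 2 and 3. The Pearson correlation was 0.7506 to 0.8098, the Spearman correlation 0.4933 to 0.5782 and the covariance 0.1245 to 0.1429. In the OsSAP11 line the auxin median was -0.008753 to 0.1094 and the endoplasmic reticulum median -0.03323 to 0.08226, and these lists were called without OsSAP11 replicate 1 (adjusted p = 0.000999) and without wild type replicate 2 (adjusted p = 0.00685). Without wild type replicate 2 the endoplasmic reticulum median was 0.08226, while its test was negative. In the OsRLCK253 line the heat shock median was -0.3564 to -0.1295, without wild type replicates 3 and 2, with its call kept, the oxidative 0.03978 to 0.6791, the endoplasmic reticulum -0.1056 to 0.02769, the cell wall 0.008536 to 0.1271 (call lost without wild type replicate 3, adjusted p = 0.0538) and the root 0.296 to 0.6223. Of these, the root list was called without OsRLCK253 replicate 2 (adjusted p = 0.0202), the oxidative list without OsRLCK253 replicate 2 or 3 (adjusted p = 0.0312 and 0.0381) and the endoplasmic reticulum list without OsSAP11 replicate 2 or 3 (adjusted p = 0.0285 and 0.00547). Without OsSAP11 replicate 2 or 3 the endoplasmic reticulum test was positive, opposite to its median of -0.034. Between the lines the medians were -0.3845 to -0.0396 for the rapid stress, -0.1195 to -0.03344 for the heat shock, -0.527 to -0.2096 for the oxidative, -0.9598 to -0.4997 for the jasmonate, 0.1851 to 0.2705 for the auxin, -1.184 to -0.6859 for the flavonoid, -0.2481 to -0.1755 for the endoplasmic reticulum, -0.2951 to -0.1797 for the cell wall, -0.1356 to -0.009139 for the SAP family and -0.5212 to -0.1948 for the root list. Without OsRLCK253 replicate 2 the heat shock, oxidative, jasmonate, cell wall, SAP family and root lists were called between the lines (adjusted p = 0.0421, 0.0306, 0.0217, 0.0146, 0.0146 and 0.0302), and so were the heat shock list without wild type replicate 1 or 3 (adjusted p = 0.0366 and 0.0393) and the oxidative list without wild type replicate 3 (adjusted p = 0.0393).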

Other observations

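The tests of families by symbol stem were chosen only after the data were seen, and the carbon starvation list was written after 4 of its genes had been seen. Beyond the lists, single members of several families changed in both lines. TET8, a tetraspanin gene, fell by 2.67 in the OsSAP11 line and fell by 2.37 in the OsRLCK253 line. UGT78D1, a flavonol glycosyltransferase gene, rose by 1.18 and 1.775, and differed between the lines (-0.59, adjusted p = 0.0448 by limma). CYP71B26 rose by 1.465 and 1.01, and XTH32, a cell wall enzyme gene, rose by 1.21 and 0.98. LCR69 fell by 1.36 and fell by 1.1, RALFL33, a gene for a signalling peptide, fell by 1.09 and fell by 0.75, and UGT73B1 fell by 1.26 and fell by 1.28.

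Of 14 measured sugar transporter genes of the SWEET family, 3 rose in the OsSAP11 line (SWEET1 by 1.32, SWEET4 by 0.91 and SWEET17 by 0.23) and none fell, with adjusted p = 0.00237 by fry and adjusted p = 0.774 with an estimated correlation. In the OsRLCK253 line 3 rose (SWEET13 by 1.16, SWEET1 by 0.69 and SWEET11 by 0.65) and none fell, with adjusted p = 0.00156 by fry and adjusted p = 0.819 with an estimated correlation. The family was gathered by gene symbol, so its counts and tests leave out SAG29, also known as SWEET15, which rose by 3.66 and 2.19 in the lines. The family's median was near 0 and turned from 0.0072 to -0.011 in the OsSAP11 line after median centring. SWEET4 differed between the lines by 1.06 (adjusted p = 0.0133). In the OsRLCK253 line fry also called the families BGLU, CYP, EXPA, GSTU, NET, TBL, TRM, UGT and XTH as higher (adjusted p from 0.00394 to 0.0341). In the OsSAP11 line it also called TRM as higher, and RALFL and TET as lower (adjusted p from 0.0121 to 0.0446). A fry call was therefore not particular to the SWEET family, and no family call held with an estimated correlation. Of 10 expansin genes of the EXPA family, 4 rose in the OsRLCK253 line, among them EXPA15 by 0.74, and none fell, with a median of 0.60 and of 0.61 under either scaling alternative (adjusted p = 0.00394 by fry, adjusted p = 0.819 with an estimated correlation). The other risen members, EXPA4, EXPA7 and EXPA8, were already given with the cell wall and root lists, so the family is no separate support. EXPA4 and EXPA7 lost their call in 7 of the 9 fits that left out 1 array. Of 8 ATG genes of autophagy, 3 fell in the OsRLCK253 line and none rose (adjusted p = 0.103 by fry). These were ATG8E, which fell by 0.82, ATG8D, which fell by 0.73, and ATG8H, which fell by 0.38. No ATG gene was called in the OsSAP11 line (adjusted p = 0.6533 by fry for the family) or between the lines (adjusted p = 0.2095 by fry). Of 10 VPS genes of vesicle sorting, 4 fell and 1 rose in the OsRLCK253 line (adjusted p = 0.011 by fry, adjusted p = 0.614 with an estimated correlation), among them VPS2.1, which fell by 0.67. Among 69 plastid genes, 5 rose and 1 fell in the OsRLCK253 line, with rbcL, psbD and psbC at 1.34, 1.06 and 0.89, and the median of -0.0060 turned positive under both scaling alternatives. The plastid group was not called by fry in this line (adjusted p = 0.6455). In the OsSAP11 line 4 rose and 1 fell, with a median of 0.042, and the group was not called (adjusted p = 0.1625 by fry). A group of 989 pseudogenes was called by fry between the lines, as lower in the OsSAP11 line (median -0.025, adjusted p = 0.0396). It was not called by fry in the OsRLCK253 line (adjusted p = 0.075), where camera with the preset correlation called it as higher (adjusted p = 1.7e-06).

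A further pattern, noticed after the data were seen, concerns genes induced by carbon starvation and darkness. Of the genes seen before the list was written, AT3G15450 and AT3G15630 are among the named genes, and AT2G20670 and AT5G19120 are not. AT3G15450, AT3G15630, AT2G20670 and AT5G19120 fell in both lines, with log2 changes from -3.61 to -2.775 in the OsSAP11 line and from -4.6 to -2.65 in the OsRLCK253 line. The 7 further listed genes, whose values had not been looked at, had a median of -0.4418 in the OsSAP11 line and -0.67 in the OsRLCK253 line, as low as in 0.3% and 0.02% of 10000 random lists of matched signal, with 3 that passed as lower and 1 as higher in the OsSAP11 line and 4 as lower in the OsRLCK253 line by limma. The random lists were drawn gene by gene, so these shares leave out any correlation among the listed genes. Both lines were compared with the same wild type arrays, so the shares are not independent of each other. ATL8 was at -0.81 and -1.27 and AKINBETA1 at -0.86 and -1.075, while AT1G76240 was higher in the OsSAP11 line (0.61) and SAG29, the called member of the fixed list of senescence and dark induced genes, rose by 3.66 and 2.19, with WRKY6, its other measured member, at -0.19 and -0.13. A candidate explanation, as a hypothesis found on the same data, is a higher sugar or light supply at harvest in both lines, which can come from the transgenes or from growth and harvest, and these arrays do not separate the sources.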
